A study of Homo sapiens with 9 samples.

How the data were processed

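The data are 9 RNA-seq libraries of LHCN-M2 immortalised human myoblasts in 3 groups of 3: the parent line with rtTA and doxycycline, the DUX4 line with doxycycline, and the DUX4 line with doxycycline and iP300w. Per the labels' protocols, libraries were made with a KAPA mRNA Hyper Prep kit and sequenced as paired ends on an Illumina NovaSeq instrument. The deposited values are whole-number counts of reads per gene symbol, 1 table per library, made by the authors. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.0.2, Subread and featureCounts 1.4.6 were used, and the builds hg38 and mm10 are named without their roles. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of genes with near-identical copies could therefore be lost or split, and reads of overlapping or antisense genes are not separable.

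Each table held the same 26485 symbols and no entry without a gene name. Of these, 6602 had 0 counts in all libraries. Symbols were matched to GENCODE release 29 on GRCh38 for coordinates (23899 matched) and to a RefSeq gene table (23758 as a symbol, 25378 with older synonyms). Coordinates are those of GENCODE and 1-based; the annotation behind the counts may place a gene's ends elsewhere. Total counts ran from 13117411 to 14508329 per library. Within groups, pairs of libraries differed beyond counting noise (chi-square per degree of freedom 2.57 to 60.5 over genes with at least 20 counts in the pair), so none was a duplicate of another. The value was at most 9.86 in the control line and at least 22.8 in the groups of the DUX4 line. The main fit nevertheless took 1 spread per gene for all groups.

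Groups were taken from the libraries' titles and characteristics. The main test was edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) with limma 3.58.1 in R 4.3.3, on the counts as deposited, with TMM factors, filterByExpr by group (minimum count 10) and 1 fit of all 9 libraries; adjusted p-values are Benjamini-Hochberg over the 13048 genes tested and the threshold was 0.05. TMM factors were 1.02 ± 0.00456 (mean ± SD) in the control line, 0.807 ± 0.0121 in the DUX4 line and 1.21 ± 0.0390 with iP300w. The 3 comparisons were the DUX4 line against the control line, the DUX4 line with iP300w against without, and the DUX4 line with iP300w against the control line. CPM values are scaled by the TMM factors. A fold against a group at 0 counts was computed against a floor of 3 counts over the group and is given as a lower bound; with 1 to 3 counts the ratio of CPM is given with a 95% counting interval.

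Moving back was counted among genes with an adjusted p under 0.05 and a log2 fold change of at least 1 in the first comparison, when the second comparison called them in the opposite direction. The share left is the log2 fold change of the last comparison divided by that of the first. Because both contrasts share the DUX4 libraries, the same counts were made on 20 simulated data sets with no inhibitor effect; on 20 with no effect at all, only the correlation and covariance of the contrasts were computed.

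The 22 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists were DUX4 target genes, myogenic regulators and myoblast markers, muscle differentiation and contractile genes, p53 targets, apoptosis regulators, the unfolded protein and integrated stress response, heat shock, oxidative stress and metallothioneins, histone acetylation, cell cycle, immediate early genes and MYC, inflammatory cytokines and NF-kB, interferon response, extracellular matrix, cholesterol synthesis, glycolysis, nonsense-mediated decay factors, cancer-testis genes, markers of fibroblasts, of epithelium and of endothelium and blood cells, and reference genes. Each list was tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, adjusted over the 22 lists within a comparison, and members were also adjusted over the list alone. The rule named the 10 largest increases and decreases among genes past the threshold with non-overlapping library ranges and a mean of at least 5 CPM in the higher group (5 for the last comparison), up to 4 members of each list with the smallest adjusted p in each of the first and second comparisons, and always DUX4, EP300, CREBBP, CDK4 and TERT; any DUX4 target may be named. The rule does not cover values of a named gene in a comparison other than its own; those given in the text were chosen after their values were seen.

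The scripts were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With edgeR, 56%, 55% and 61% of the 2-fold and 85%, 84% and 90% of the 4-fold changes were recovered in the first, second and last comparison (12332, 12312 and 12330 genes tested), with 6, 6 and 11 false calls. Alternatives were DESeq2 1.42.0, limma-voom, other scalings (size factors by relative log expression, total counts alone, upper quartile), other filters on low counts, other thresholds, fits of only the 6 libraries compared, and leaving out each library in turn. Offsets from 20 bins of transcript GC content per library, and leaving out libraries 1 and 4 together, were added after seeing the data. Figures were drawn with Python 3.11.15. Levels of genes that would bear on the sex of a donor are not reported here.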

Results

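Messenger RNA was sequenced from 9 libraries of LHCN-M2 cells, an immortalised line of human myoblasts (muscle precursor cells), in 3 groups of 3. Cells of the DUX4 line carried the doxycycline-dependent activator rtTA and a DUX4 gene under its control, and received doxycycline alone (libraries 1, 2 and 3) or together with iP300w (libraries 4, 5 and 6). iP300w is named in the series as an inhibitor of p300, a histone acetyltransferase encoded by EP300. The control was the parent line, with rtTA but without the DUX4 gene, also given doxycycline (libraries 24, 25 and 26). DUX4 is a transcription factor of the cleavage-stage embryo whose misexpression in muscle is linked to facioscapulohumeral muscular dystrophy. Total counts ran from 13117411 to 14508329 per library, and 13048 of 26485 gene symbols had enough counts for testing. The first principal component of the log2 CPM values held 68.3% of the variance and the second 19.8%. Levels are CPM, counts scaled to a common library total, with trimmed-mean (TMM) factors, given as mean ± SD over the 3 libraries of a group, log2 fold changes carry their SE, and adjusted p-values are from edgeR's quasi-likelihood test. The labels do not say whether the libraries of a group came from separate cultures, so these p-values may measure only technical spread. Intervals and floors given for low counts cover counting error only.

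DUX4 itself (GRCh38 chromosome 4, 190173774 to 190185942, plus strand) had 0 counts in all 9 libraries. The 3 counts that an observed 0 allows correspond to 0.177 to 0.283 CPM in these libraries. The gene lies in a near-identical repeat array and the transgene may differ from the annotated copy, so a count of 0 does not mean absence and does not check the labels. ZSCAN4, a gene DUX4 is known to activate, had more counts in each of the 6 libraries of the DUX4 line than in any control library.

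The first comparison, the DUX4 line against the control line with doxycycline in both, asked what induced DUX4 changes in myoblasts. Transcripts of the cleavage-stage embryo appeared and those of the myoblast factors MYOD1 and MYF5 fell. All 35 measured members of the list of DUX4 target genes rose, among them ZSCAN4, a zinc finger gene of the early embryo, from 0.448 ± 0.353 to 3036 ± 488 CPM. MYOD1, the muscle determination factor, fell 225-fold, from 153 ± 44.5 to 0.676 ± 0.438 CPM, and its relative MYF5 fell 34.1-fold, from 286 ± 56.4 to 8.41 ± 4.46 CPM. Across the 13048 genes tested, 4659 were higher and 4680 lower at an adjusted p under 0.05, of which 2976 and 3049 also changed at least 2-fold. Higher genes were 49.9% of those changed with TMM scaling, 36.8% with total counts alone and 39.5% with upper-quartile factors, because these scalings moved the median log2 fold change of all genes from -0.03 to -0.37 and -0.30.

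The DUX4 target list held 43 genes, of which 41 had a symbol in the data and 35 enough counts; all 35 also rose when adjusted over the list alone. Measured targets averaged at most 0.448 CPM in the control line, so they passed the count filter through libraries of the DUX4 line. This favours a rise in the member counts and set tests, but does not set the size of the folds. Their median log2 fold change was 12.42, or 11.55 with genes at 0 in the control line set at their lower bound. RFPL4B, of the ret finger protein-like family, stood at 3599 ± 82.1 CPM in the DUX4 line against 0.257 ± 0.161 CPM in the control line. DUXA and LEUTX, paired-like homeobox genes of the early embryo, reached 3535 ± 1465 and 1399 ± 511 CPM, from 0.231 ± 0.168 and 0.164 ± 0.109 CPM. KDM4E, a histone demethylase gene, reached 521 ± 91.9 CPM, and its ratio of 11084 (95% counting interval 3068 to 91533) rested on 2 counts in the control line. CCNA1, the germ cell cyclin A1, and SLC34A2, a sodium-phosphate cotransporter, reached 1584 ± 1001 and 1999 ± 960.1 CPM. Some of these folds move when single libraries are left out: the log2 fold change of ZSCAN4 was 12.71 (13.54 without control library 25), of DUXA 13.83 (14.49 without 26) and of CCNA1 12.30 (11.66 without DUX4 library 3). Without control library 25 the ratio was 13290.4 for LEUTX on 3 control counts (95% counting interval 4547 to 64449), against 8495 with it, and 28352 for SLC34A2 on 2 control counts (7848 to 234119), against 16914. The set test camera gave the list an adjusted p of 2.74e-23 against all other genes; adjusted p = 0.695 with an estimated correlation between members (0.612). The test fry, which asks only whether the members move 1 way, gave 0.000122 and passed 14 of the 22 lists. ZSCAN4 lies on chromosome 19 from 57668935 to 57679152 (plus strand), LEUTX on 19 from 39776595 to 39786167 (plus strand) and DUXA on 19 from 57154021 to 57167443 (minus strand). Values of single members of the PRAMEF, TRIM, RFPL, MBD3L and ZNF705 families are uncertain, since near-identical copies share reads and the rule for such reads is not given in the sources used here.

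**Figure D1:**
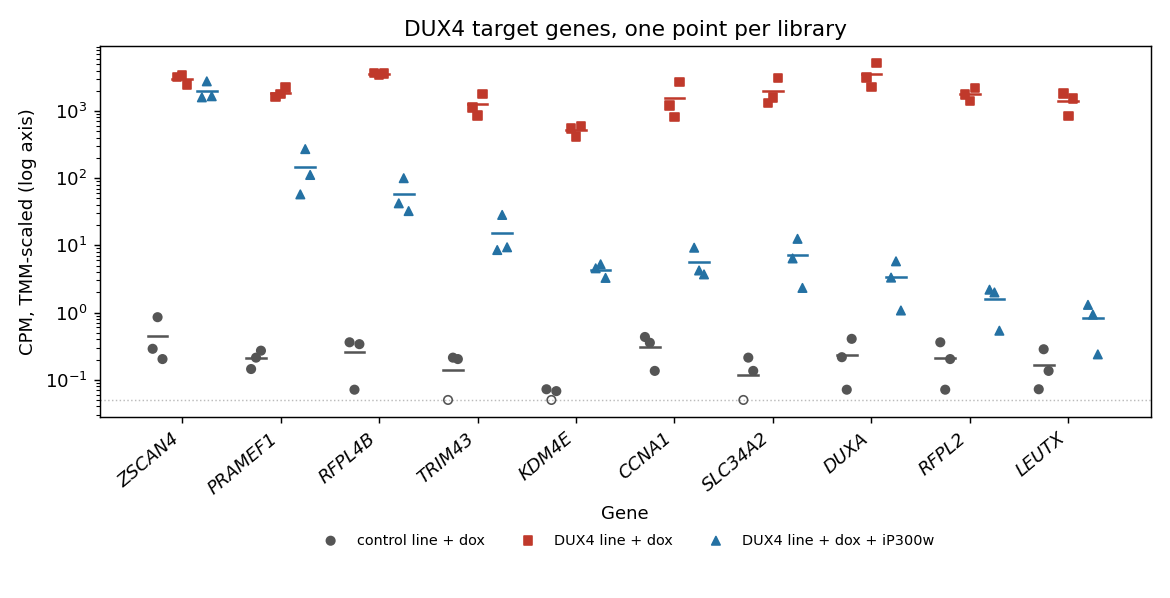
CPM (TMM-scaled, log axis) of 10 DUX4 target genes in each of the 9 libraries, with short lines at group means and open symbols at the dotted line for libraries with 0 counts. ZSCAN4 stood at 2005 ± 656 CPM (mean ± SD) with iP300w against 3036 ± 488 without it, while LEUTX stood at 0.825 ± 0.540 against 1399 ± 511.

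Outside that list, the largest increases with at least 5 CPM included ZNF705A, a zinc finger gene, and MRAP2, an accessory protein of melanocortin receptors. Both had 0 counts in the control line and were at least 2649-fold and 2122-fold higher in the DUX4 line, at 186 ± 22.5 and 149 ± 79.0 CPM. Without control library 26 these bounds were 1732-fold and 1388-fold; a bound falls by construction when a library at 0 counts is left out. Among the largest decreases, ATOH8, a basic helix-loop-helix factor, fell from 124 ± 10.3 to 1.01 ± 0.566 CPM. SNAI2, a repressor of epithelial genes, fell from 350.2 ± 24.9 to 3.33 ± 1.95 CPM. NOG, a secreted antagonist of bone morphogenetic proteins, fell from 52.1 ± 6.17 to 0.709 ± 0.450 CPM. IP6K3, an inositol hexakisphosphate kinase, fell from 52.8 ± 3.26 to 0.328 ± 0.359 CPM. COL4A5, a type IV collagen chain, had 0 counts in the DUX4 line and was at least 211-fold lower than in the control line (19.2 ± 3.79 CPM), or 140.5-fold without DUX4 library 1 and 139-fold without 2. The log2 fold change of NOG was -6.20, or -6.83 without DUX4 library 3, and the fold of IP6K3 was 157.5, or 379.6 on 3 counts (counting interval 129.7 to 1842) without DUX4 library 2.

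Of 19 measured myogenic regulators and myoblast markers, 14 fell, 2 rose and 3 did not pass (fry adjusted p 0.000122, camera 0.0507); adjusted p = 0.695 with an estimated correlation. Camera passed this list with relative log expression factors (0.0467), with no low-count filter (0.00179) and without each single library except DUX4 library 2 (0.0195 to 0.0460). For this and the following lists the counts adjusted over the list alone were the same unless given, and members not counted as risen or fallen did not pass. Of 17 muscle differentiation and contractile genes, 5 fell, 2 rose and 10 did not pass (4 fell when adjusted over the list alone). ACTC1, cardiac alpha-actin, fell 4.33-fold to 127 ± 9.20 CPM, and CAV3, caveolin of muscle membranes, fell from 14.4 ± 3.85 to 0.618 ± 0.431 CPM. KLHL41, a sarcomere-associated protein, rose from 28.2 ± 16.0 to 182 ± 125 CPM. The log2 fold change of CAV3 was -4.54, or -5.12 without DUX4 library 3, and that of KLHL41 2.69, or 1.97 without DUX4 library 1. MYOD1 lies on chromosome 11 from 17719568 to 17722131 and MYF5 on 12 from 80716912 to 80719673, both on the plus strand.

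Genes of cell death and stress moved in both directions, as did the genes tested at large, of which 71.6% changed with DUX4. Member counts of these and the following lists are to be read beside that share, and camera passed none of these lists in the main fit. Of 22 apoptosis regulators 8 rose and 10 fell; BCL2L11, the pro-apoptotic BIM, rose 14.6-fold to 44.8 ± 6.68 CPM. In the same list CASP8, an initiator caspase, fell 17.6-fold and BCL2L1, the anti-apoptotic BCL-X, fell 14.9-fold. Of 21 p53 targets 5 rose and 9 fell, with ZMAT3 at 1.20 ± 0.11 and BAX at -1.45 ± 0.15 log2 fold change. Of 20 genes of the unfolded protein and integrated stress response 10 rose and 2 fell; the chaperone cofactor DNAJB9 rose 9.47-fold, and DDIT4, an inhibitor of mTORC1, fell 102-fold. Of 16 heat shock genes 9 rose and 3 fell (4 fell when adjusted over the list alone), with HSPA4L at 4.63 ± 0.26 and the co-chaperone CHORDC1 at 3.03 ± 0.17. Of 18 genes of oxidative stress and metallothioneins 5 rose and 8 fell; MT1E, a metallothionein, fell 70.4-fold and GCLC, of glutathione synthesis, rose 6.79-fold.

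Of 26 writers, erasers and readers of histone acetylation 10 rose and 10 fell. EP300 (chromosome 22, 41091786 to 41180079, plus strand) rose from 105 ± 4.84 to 313 ± 7.26 CPM (adjusted p 3.17e-06), and its paralog CREBBP rose 2.08-fold. The deacetylase gene SIRT1 rose 8.86-fold, while the class II deacetylases HDAC5 and HDAC7 fell 14.7-fold and 5.89-fold. Of 30 cell cycle genes 9 rose and 9 fell; TOP2A, the DNA topoisomerase of dividing cells, fell 2.39-fold and CCNE1, cyclin E1, rose 6.76-fold. CDK4, a cyclin-dependent kinase, fell 2.37-fold. TERT, the telomerase reverse transcriptase, had a log2 fold change of -0.91 ± 0.31 (adjusted p 0.0240), a call lost without DUX4 library 2 or control library 24 or 25 (adjusted p 0.0693, 0.0542 and 0.0624) and with GC offsets (log2 fold change -0.10), and without libraries 1 and 4 together (0.0521). Of 17 immediate early genes and MYC 9 rose and 3 fell, with FOS up 71.2-fold to 90.4 ± 12.7 CPM and FOSL1 down 25.3-fold. Of 13 inflammatory and NF-kB genes 3 rose and 4 fell; NFKBIA, the inhibitor of NF-kB, fell 2.35-fold. Of 20 interferon response genes 8 rose and 3 fell (2 fell when adjusted over the list alone), with IFIT1 down 5.60-fold.

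Of 27 extracellular matrix genes 16 rose and 2 fell; COL6A1, a collagen VI chain, rose 2.90-fold and THBS1, thrombospondin, fell 5.38-fold. Of 20 cholesterol synthesis genes 8 rose and 6 fell, the sterol carrier STARD4 rising 14.4-fold. Of 20 glycolysis genes 1 rose and 12 fell, with HK1, hexokinase, down 2.62-fold and PFKFB4 down 20.3-fold. Of 14 factors of nonsense-mediated decay 8 rose and 4 fell; EIF4A3 rose 2.89-fold and CASC3 fell 3.89-fold, both parts of the exon junction complex. Both cancer-testis genes measured of 26 listed, BRDT and TEX15, rose. BRDT rose by at least 175-fold from 0 counts, or at least 114-fold without control library 26. Without DUX4 library 1 it rose at least 99.7-fold, and the log2 fold change of TEX15 was 6.44 in place of 7.14. Among markers of cell types a culture could also hold, 2 of 10 fibroblast markers rose and 4 fell, with the receptor gene PDGFRA up 55.9-fold and PDGFRB down 8.74-fold. Both epithelial markers measured of 11 listed rose. BRDT and the epithelial marker KRT8 had 0 counts in the control line. They passed the count filter only through the DUX4 line, which favours a rise. KRT18 reached 6.62 ± 1.37 CPM (ratio 35.2, or 61.5 on 3 control counts, counting interval 20.8 to 300.3, without control library 26). Of 4 endothelial and blood cell markers 2 rose and 1 fell. Of 14 reference genes 5 rose and 3 fell. Camera passed only the DUX4 target list in this comparison; adjusted p for the other 21 ran from 0.0507 to 0.802. Besides the myogenic list, glycolysis passed without DUX4 library 3 (0.0299), iP300w library 4 (0.0337) or 5 (0.0352) or control library 24 (0.0483) and with no low-count filter (0.00179), and heat shock without DUX4 library 1 (0.0365) or 2 (0.0414); adjusted p = 0.897 with an estimated correlation for both. The line and the transgene changed together, so differences between the 2 lines other than DUX4 are part of every value here.

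The second comparison, the DUX4 line with iP300w against the same line without it, asked what the p300 inhibitor does to the DUX4 response. Most of the embryonic transcripts fell steeply, and among the 35 listed targets measured ZSCAN4 changed least. DUX4 itself had 0 counts in every library, so whether its own level differed with iP300w was not measured. Of the 35 DUX4 targets 34 fell (35 when adjusted over the list alone), by a median log2 fold change of -7.84: LEUTX went from 1399 ± 511 to 0.825 ± 0.540 CPM and DUXA from 3535 ± 1465 to 3.39 ± 2.36 CPM. ZSCAN4 stood at 2005 ± 656 CPM with the inhibitor against 3036 ± 488 without it, a log2 fold change of -0.60 ± 0.26 (adjusted p 0.0703), which did not pass. EGR1 and ICAM1 rose above both other groups. Across 13048 genes 3972 were higher and 4463 lower, 2279 and 2339 of them at least 2-fold. Higher genes were 47.1% of those changed with TMM scaling, 75.5% with total counts alone (6784 higher, 2207 lower) and 62.9% with upper-quartile factors; the median log2 fold change of all genes was -0.05, 0.54 and 0.26 in turn, so directions are relative to the TMM scaling.

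Targets lost different shares of their level. With iP300w the 35 genes kept a median of 0.406% of their CPM in the DUX4 line, 20 kept under 1% and 34 under 10%. Targets near 0 with the inhibitor passed the count filter through the libraries without it, which favours a fall. ZSCAN4 kept 66.0%, PRAMEF1 7.78%, RFPL4B 1.62%, TRIM43 1.22%, KDM4E 0.835%, CCNA1 0.361% (log2 fold change -8.11, or -7.47 without DUX4 library 3) and LEUTX 0.0589%. RFPL3 had 0 counts with the inhibitor and was at least 237-fold lower, or 156.6-fold and 157.2-fold without iP300w library 4 or 6. The camera adjusted p of the list was 1.31e-23; adjusted p = 0.412 with an estimated correlation (0.527), and fry gave 6.29e-05 and passed 8 of the 22 lists. The ZSCAN4 difference passed with DESeq2 (adjusted p 0.0430), limma-voom (0.0280) and without iP300w library 5 (log2 fold change -0.90, adjusted p 0.0104), and was -0.02 with total counts alone. Without iP300w library 5 the log2 fold change of PRAMEF1 moved from -3.68 ± 0.48 to -4.47, of TRIM43 from -6.36 ± 0.55 to -7.14, of RFPL4B from -5.95 ± 0.43 to -6.59 and of DUXA from -10.03 ± 0.62 to -10.64.

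Among other large decreases with iP300w, DDX4, the germ cell RNA helicase, stood at 62.3 ± 48.7 CPM without the inhibitor and its ratio of 1564 (95% counting interval 432 to 12924) rested on 2 counts with it. UTS2, the peptide urotensin, RGS13, a regulator of G-protein signalling, and HOOK1, a microtubule-binding protein, had 0 counts with iP300w and were at least 237-fold, 262-fold and 260.4-fold lower. Both measured cancer-testis genes fell, BRDT at least 204-fold. BRDT had 0 counts in both other groups and passed the count filter only through the DUX4 libraries without iP300w, which favours a fall. Among the largest increases, AKAP5, an anchoring protein of protein kinase A, rose from 0.703 ± 0.236 to 18.9 ± 2.26 CPM, and ABCA3, a lipid transporter, from 0.182 ± 0.0881 to 6.92 ± 1.12 CPM. SAPCD2 rose from 1.31 ± 0.139 to 27.0 ± 7.55 CPM and the WNT pathway factor LEF1 from 0.278 ± 0.284 to 5.71 ± 0.706 CPM. Without DUX4 library 1 the ratio for DDX4 was 945 (counting interval 261 to 7819.6), and the lower bounds were 142-fold for UTS2, 129.9-fold for RGS13, 146-fold for HOOK1 and 116-fold for BRDT. Without iP300w library 4 or 6 they were 156 and 157 for UTS2, 173 and 174 for RGS13, 172 and 173 for HOOK1 and 134.6 and 135.2 for BRDT, and the DDX4 ratio was 1037 (287 to 8567) without 6. The ratio for LEF1 was 20.8, or 42.4 on 3 counts (counting interval 14.4 to 207) without DUX4 library 3. The RGS13 call was lost with no low-count filter (adjusted p 0.0630).

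**Figure D2:**
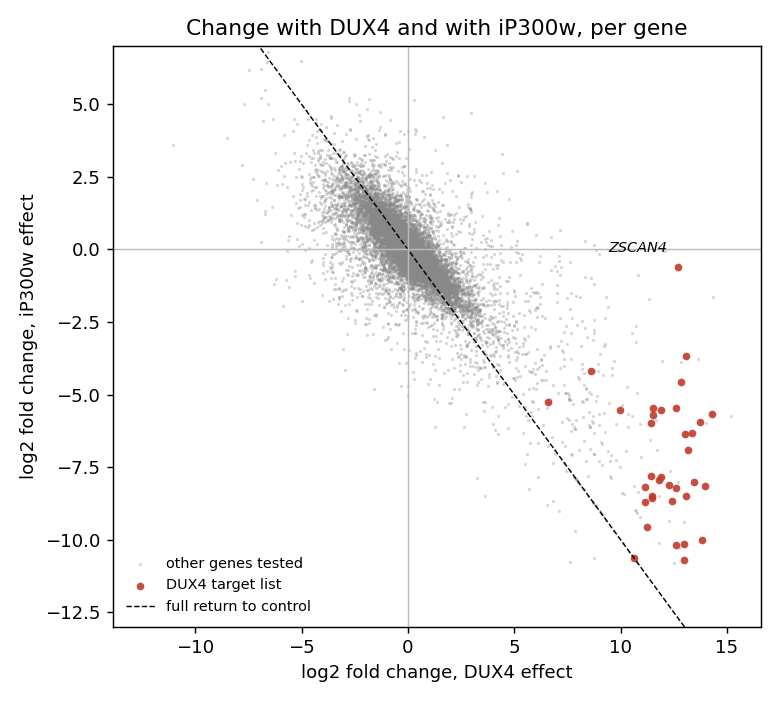
Log2 fold change with iP300w (vertical) against log2 fold change with DUX4 (horizontal) for each of 13048 genes tested; red points are the 35 DUX4 targets, and the dashed line marks a full return to the control line. ZSCAN4 sits at 12.71 and -0.60, above the other targets, whose vertical median with ZSCAN4 included is -7.84. The correlation was -0.78 here. Simulations with no inhibitor effect gave a mean of -0.09 with the DUX4 effect kept and -0.52 with no effect at all.

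Of 19 myogenic regulators and myoblast markers 6 rose and 5 fell. MYOD1 rose 7.44-fold to 5.03 ± 3.52 CPM (adjusted p 0.00504; log2 fold change 2.89, or 2.25 without iP300w library 4) and MYF5 2.72-fold to 22.9 ± 5.25 CPM (adjusted p 0.00383), both still far under the control line at 153 ± 44.5 and 286 ± 56.4 CPM. CDH15, the muscle cadherin, fell further, from 64.4 ± 7.41 to 34.0 ± 1.11 CPM (its fall with DUX4 was lost with GC offsets, log2 fold change -0.18 in place of -0.91). MEF2A, a partner of the muscle determination factors, rose from 39.1 ± 6.33 to 70.5 ± 13.9 CPM. Of 17 differentiation and contractile genes 1 rose and 6 fell; KLHL41 fell 15.4-fold (log2 fold change -3.95, or -3.23 without DUX4 library 1), CHRNA1, the acetylcholine receptor subunit, 4.28-fold and ACTC1 2.69-fold. Of 27 extracellular matrix genes 21 fell and none rose: TIMP3, a metalloproteinase inhibitor, fell 4.14-fold to 36.2 ± 13.3 CPM, SPARC 2.75-fold and COL6A2 2.01-fold. Camera passed this list (adjusted p 0.0112), a call lost without DUX4 library 3 (0.0830); adjusted p = 0.994 with an estimated correlation. Of 10 fibroblast markers 2 rose and 5 fell, PDGFRA falling 48.8-fold to 2.46 ± 1.11 CPM and TWIST2, a mesenchymal transcription factor, rising 7.85-fold (log2 fold change 2.97, or 2.21 without libraries 1 and 4).

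With iP300w 64.6% of all genes tested changed, and member counts of the lists are to be read beside that share. Among apoptosis regulators 8 rose and 7 fell. CASP8 rose 10.7-fold, and the anti-apoptotic genes BCL2L1 and XIAP rose 3.24-fold and 3.17-fold. Of 21 p53 targets 8 rose and 5 fell; MDM2, the p53 ubiquitin ligase, fell 2.26-fold and BTG2, an antiproliferative factor, rose 6.24-fold. Of 20 genes of the unfolded protein and integrated stress response 3 rose and 9 fell, with the chaperone HSPA5 down 2.81-fold and DDIT4 up 4.94-fold. Of 16 heat shock genes 2 rose and 9 fell, CHORDC1 falling 3.38-fold and DNAJA1 2.45-fold. Of 18 genes of oxidative stress and metallothioneins 5 rose and 7 fell (6 rose when adjusted over the list alone); NQO1, a quinone reductase, fell 2.22-fold and SOD2, mitochondrial superoxide dismutase, 2.65-fold.

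Of 26 histone acetylation genes 11 rose and 9 fell; KAT2A, an acetyltransferase, rose 3.40-fold, HDAC1 rose 2.05-fold and SIRT1 fell 3.25-fold. EP300 stood at 209 ± 35.0 CPM, a log2 fold change of -0.58 ± 0.12 (adjusted p 0.00215); it was 0.00 with total counts alone, and the call was lost with upper-quartile factors (adjusted p 0.0541) and with GC offsets (log2 fold change -0.27, adjusted p 0.0740). CREBBP had a log2 fold change of -0.27 ± 0.12 (adjusted p 0.0782), which turned to 0.31 with total counts alone and passed without iP300w library 5 (-0.42, adjusted p 0.00549). CDK4 stood at 0.18 ± 0.15 (adjusted p 0.316), and passed with total counts alone (0.77), upper-quartile factors (0.49) and without DUX4 library 3 (0.34, adjusted p 0.0496). TERT stood at -0.97 ± 0.33 (adjusted p 0.0249), a call lost with total counts alone (0.320), upper-quartile factors (0.0999) and a fit of only the 2 groups compared (0.0863). It was also lost without DUX4 library 1 or 3, or iP300w library 4 or 5 (adjusted p 0.0542, 0.0946, 0.0731 and 0.0810), and without libraries 1 and 4 together (0.118). Of 30 cell cycle genes 6 rose and 9 fell, TOP2A rising 2.48-fold and CCNE1 falling 4.29-fold. Of 17 immediate early genes and MYC 5 rose and 4 fell; EGR1, a growth response factor, rose from 250.1 ± 86.0 to 745 ± 73.6 CPM, MYC fell 8.65-fold to 3.83 ± 1.59 CPM, and KLF4, a Krüppel-like factor, fell 9.93-fold.

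Of 13 inflammatory and NF-kB genes 5 rose and 2 fell (1 fell when adjusted over the list alone); ICAM1, an adhesion molecule, rose 6.22-fold to 142 ± 40.1 CPM and NFKB2 2.79-fold. Of 20 interferon response genes 2 rose, OAS3 (4.16-fold) and IFIT1 (3.18-fold), and 2 fell (1 when adjusted over the list alone). Of 20 cholesterol synthesis genes 8 rose and 6 fell, with FDFT1, squalene synthase, up 2.09-fold. Of 20 glycolysis genes 7 rose and 4 fell, HK1 rising 2.07-fold and PKM, pyruvate kinase, falling 2.05-fold. Of 14 nonsense-mediated decay factors 3 rose and 8 fell, with EIF4A3 down 2.60-fold and CASC3 up 2.33-fold. Neither measured epithelial marker passed, and 2 of 4 endothelial and blood cell markers fell. Of 14 reference genes none rose and 9 fell, led by TFRC, the transferrin receptor, which fell 8.83-fold from 736 ± 134 to 83.4 ± 15.5 CPM. Their median log2 fold change was -0.57, and fry gave them an adjusted p of 1.13e-05, the lowest of the 22 lists. Total counts alone moved the median of all genes from -0.05 to 0.54, a shift of about that size, so this fall depends on the TMM scaling. Besides the DUX4 targets and the extracellular matrix, camera passed none of the other 20 lists (adjusted p 0.0900 to 0.993). It passed the contractile list with total counts alone (0.0419) and the reference genes with no low-count filter (0.0162); adjusted p = 0.994 and 0.412 with an estimated correlation. The design holds no control line with iP300w, so effects of the inhibitor on DUX4-driven and on other transcription cannot be separated here.

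**Figure D3:**
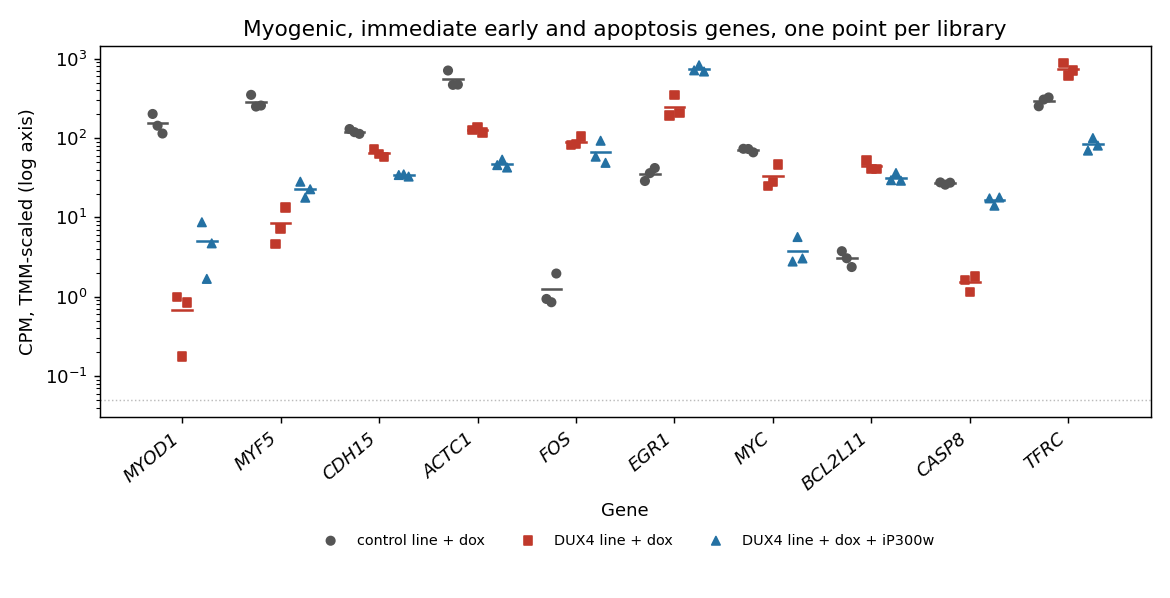
CPM (TMM-scaled, log axis) of 10 myogenic, immediate early, apoptosis and reference genes in each of the 9 libraries, with short lines at group means. MYOD1 stood at 153 ± 44.5 (mean ± SD), 0.676 ± 0.438 and 5.03 ± 3.52 CPM in the control line, the DUX4 line and the DUX4 line with iP300w, and EGR1 at 35.7 ± 6.60, 250.1 ± 86.0 and 745 ± 73.6.

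The series also asks how far the inhibitor undoes the change that DUX4 makes. Of the 2976 genes that rose at least 2-fold with DUX4, 2461 (82.7%) fell with iP300w, 455 did not pass and 60 rose further. Of the 3049 that fell at least 2-fold, 2190 (71.8%) rose with iP300w, 718 did not pass and 141 fell further. PDGFRA ended at 2.46 ± 1.11 against 2.14 ± 0.529 CPM (adjusted p 0.780) and TOP2A at 1031 ± 60.6 against 992 ± 19.9 CPM (adjusted p 0.706), though TOP2A passed with total counts alone (log2 fold change 0.30, adjusted p 0.0452). BCL2L11 stayed 10.3-fold above the control line and FOS 52.4-fold above it. The median share of the DUX4 log2 fold change still left was 0.339 among genes that rose (quartiles 0.157 and 0.556) and 0.376 among those that fell (0.0961 and 0.679), and 1617 (54.3%) and 1671 (54.8%) remained apart from the control line in the same direction. With total counts alone 1543 and 3414 genes moved back and the shares left were 0.525 and 0.164, so the balance between the directions depends on the scaling.

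Both contrasts use the same 3 DUX4 libraries, which alone pulls them toward opposite signs. In 20 simulated data sets with the DUX4 effect kept and no inhibitor effect, at most 1 gene that rose and none that fell moved back, and the mean shares left were 0.991 and 0.983. Across genes, which are not independent replicates, the fold changes of the contrasts correlated at -0.78. The mean was -0.09 in the simulations with the DUX4 effect kept and -0.52 with no effect at all. The covariance was -2.54, against -0.06 with the DUX4 effect kept. With no effect at all it was -0.05, a difference of -2.49. Of genes called in opposite directions, 3438 were up with DUX4 and down with iP300w, where independent lists of those sizes share 1593.6, and 3075 the reverse, where they share 1424.7. The 3 libraries cannot be split into sets of at least 2, so part of this excess may come from the shared libraries. The simulations with the DUX4 effect kept, where at most 1 gene moved back, argue against the shared libraries as the source of most of it. They drew libraries independently, and this overlap was not counted in them.

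The last comparison, the DUX4 line with iP300w against the control line, asked what remained; most genes given for it were named by the rule for the other comparisons. ZSCAN4 stood at 2005 ± 656 CPM against 0.448 ± 0.353, and 20 of the 35 targets stayed above the control line (21 when adjusted over the list alone), with a median log2 fold change of 4.41, or 3.05 with genes at 0 counts at their bound. MYOD1 was 30.3-fold lower at 5.03 ± 3.52 CPM, and MYF5 12.5-fold lower. The log2 fold change of ZSCAN4 was 12.11, or 12.95 without control library 25, and that of MYOD1 -4.92, or -5.57 without iP300w library 4. Across all genes 3182 were higher and 3179 lower, 1264 and 1552 of them at least 2-fold; higher genes were 50.0% of those changed, 68.6% with total counts alone and 53.2% with upper-quartile factors, at median log2 fold changes of 0.01, 0.26 and 0.05.

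PRAMEF1, at 147 ± 111 CPM, stood 667-fold above the control line, ZNF705A at least 856-fold and PRAMEF7 at least 100.1-fold. KDM4E stood at 4.35 ± 0.989 CPM and DUXA at 3.39 ± 2.36 CPM, log2 fold change 3.80 ± 0.84 (3.18 without iP300w library 5 and 4.47 without control library 26). LEUTX, at 0.825 ± 0.540 CPM, did not pass (adjusted p 0.0580), though it did with DESeq2 (0.0121), total counts alone (0.0325), or without DUX4 library 2 (0.0273) or iP300w library 6 (0.0181). Of the 20 higher targets PRAMEF20, TRIM49, TRIM49B and TRIM64B lost their call when single libraries were left out (without iP300w library 5, adjusted p 0.103, 0.122, 0.108 and 0.0815, and without each control library in turn, 0.0657 to 0.0981). TRIM49 and TRIM49B also lost it without DUX4 library 2 (0.0565 and 0.0505) or iP300w library 4 (0.101 and 0.0519). Without iP300w library 5 the log2 fold change of PRAMEF1 was 8.59 in place of 9.38, and the lower bound for PRAMEF7 was 56.6-fold. Without control library 26 that bound was 65.5-fold, and the bound for ZNF705A 560.0-fold. Among the largest decreases, HAS2, a hyaluronan synthase, stood at 1.84 ± 0.619 CPM against 201 ± 13.7 in the control line, DMBT1 at 0.200 ± 0.0876 against 47.5 ± 4.29 CPM and NOG at 0.341 ± 0.0262 against 52.1 ± 6.17 CPM.

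Camera passed 9 lists in this comparison with its preset correlation and none with an estimated one, and fry passed 10. For the DUX4 targets the adjusted p was 2.19e-09; adjusted p = 0.563 with an estimated correlation. Of 19 myogenic regulators 12 were lower and none higher (1 higher when adjusted over the list alone), at 4.11e-05; adjusted p = 0.231 with an estimated correlation. Of 17 differentiation and contractile genes 10 were lower (11 over the list alone), ACTC1 by 11.7-fold, at 0.00172; adjusted p = 0.563 with an estimated correlation. Of 20 glycolysis genes 14 were lower and 1 higher (2 higher over the list alone), PKM by 1.82-fold, at 0.00453; adjusted p = 0.563 with an estimated correlation. Both epithelial markers measured of 11 listed were higher, KRT18 at 4.96 ± 1.08 CPM, at 0.0350, with adjusted p = 0.448 with an estimated correlation. KRT8, the other, had 0 counts in the control line and passed the count filter only through the DUX4 line, which favours this call. Of 17 immediate early genes 9 were higher and 5 lower (10 higher over the list alone), EGR1 20.9-fold higher and MYC 18.5-fold lower, at 0.0463; adjusted p = 0.676 with an estimated correlation. Of 10 fibroblast markers 6 were lower, THY1 by 3.29-fold, at 0.0463; adjusted p = 0.448 with an estimated correlation. Of 18 oxidative stress genes 9 were lower and 3 higher, MT1E 15.3-fold lower, and of 14 reference genes 7 were lower, TFRC by 3.53-fold, each at 0.0493; adjusted p = 0.448 with an estimated correlation for both.

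Those last 5 calls, from 0.0350 to 0.0493, were each lost when single libraries were left out: the epithelial list without any of DUX4 libraries 1 to 3, iP300w libraries 4 to 6 or control library 24 (adjusted p 0.0538 to 0.200), the immediate early list without DUX4 library 1 or 3, iP300w library 5 or control library 24 (0.0554 to 0.208), and the fibroblast list without DUX4 library 3 or iP300w library 5 (0.0534 and 0.0554). The oxidative stress list lost its call without DUX4 library 1 or 3 or iP300w library 4 or 6 (0.0538 to 0.0773) and the reference genes without DUX4 library 1 or 3, iP300w library 5 or 6 or control library 24 (0.0538 to 0.0806). Camera passed none of the other 13 lists (adjusted p 0.0510 to 0.959). Of all genes tested 48.8% changed in this comparison, and member counts of the lists are to be read beside that share. Without DUX4 library 2, iP300w library 4 or control library 25 or 26 it also passed heat shock (0.0371 to 0.0429) and the interferon response (0.0377 to 0.0411), and without iP300w library 6 the extracellular matrix (0.0464); adjusted p = 0.563, 0.752 and 0.906 with an estimated correlation. Of 22 apoptosis regulators 6 were higher and 6 lower, with BCL2L1 4.59-fold lower, and of 21 p53 targets 3 were higher and 5 lower. Of 20 genes of the unfolded protein and integrated stress response 9 were higher and 4 lower, DDIT4 20.6-fold lower, and of 16 heat shock genes 8 were higher and 2 lower (4 lower over the list alone), HSPA4L 11.6-fold higher. Of 26 histone acetylation genes 7 were higher and 8 lower, with EP300 2.00-fold and CREBBP 1.72-fold higher. Of 30 cell cycle genes 6 were higher and 9 lower; CDK4 was 2.09-fold lower. Of 13 inflammatory genes 4 were higher and 4 lower, ICAM1 22.3-fold higher, and of 20 interferon response genes 8 were higher and 1 lower. Of 27 extracellular matrix genes 8 were lower and 1 higher (7 lower over the list alone), THBS1 by 9.98-fold. Of 20 cholesterol synthesis genes 7 were higher and 1 lower (6 higher over the list alone), of 14 nonsense-mediated decay factors 2 were higher and 1 lower (1 higher over the list alone), 1 of 4 endothelial and blood cell markers was lower, and neither cancer-testis gene passed.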

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

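Offsets for GC content and leaving out libraries 1 and 4 together were chosen after the results were seen; the other alternatives were planned. Across alternatives 117 of 126 recomputed counts of changed genes stayed within 1.5 times the reported count and 9 did not. For named genes 6152 recomputed calls were the same, 78 were lost, 26 were gained and 4 turned sign; for lists other than the DUX4 targets 851 were the same, 44 were lost and 50 gained. Requiring at least a 2-fold change left 2976 higher and 3049 lower genes with DUX4, 2279 and 2339 with iP300w, and 1264 and 1552 in the last comparison, where an adjusted p under 0.01 left 2115 higher; fewer genes can pass these by construction. With total counts alone the iP300w counts were 6784 and 2207, genes moved back 1543 (higher with DUX4) and 3414 (lower), and shares left 0.525 and 0.164; CREBBP turned to 0.31, EP300 to 0.00167, HLA-C to 0.10 and YWHAZ to 0.0118 with iP300w. This scaling moves every log2 fold change of the comparison by 1 amount. Among genes changed at least 4-fold with DUX4, 1144 and 909 moved back and the share left was 0.434 for lower genes; the sets are smaller by construction. For lower genes the share left was 0.357 with GC offsets and 0.429 without libraries 1 and 4; the cause was not tested. The DUX4 target list passed with fry, and with camera under relative log expression factors, total counts alone, no low-count filter and each library left out, but not with an estimated correlation (adjusted p 0.695, 0.412 and 0.563), which widens the test by its construction. Leaving out single libraries gave 4376 to 4816 higher and 4286 to 4780 lower genes with DUX4, 3588 to 3996 and 4090 to 4458 with iP300w, 2397 to 3572 and 2524 to 3587 in the last comparison, 2335 to 2559 and 1970 to 2275 genes moved back, and shares left of 0.316 to 0.351 (higher) and 0.352 to 0.409 (lower). No paired analysis was run, because the groups share no replicate number in the labels. The fits and the simulations treat libraries as independent, though libraries 1 and 4, 2 and 5, and 3 and 6 deviated together. The p-values with iP300w therefore ignore this pairing. Depth limits genes at 0 counts in a group, whose folds are lower bounds.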

Other observations

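The splits of the libraries were planned; the other tests in this part were chosen after the result was seen, as were NDN, BACE2 and PCOLCE2, which lie outside the rule for named genes. Some genes with iP300w lay outside both other groups. 975 genes were higher than in both the control line and the DUX4 line, 332 of them at least 2-fold in each, and for 513 of the 975 the DUX4 effect itself had not passed. EGR1 reached 745 ± 73.6 CPM, 20.9-fold above the control line and 2.98-fold above the DUX4 line, and ICAM1 reached 142 ± 40.1 CPM, 22.3-fold and 6.22-fold above them. AKAP5 and ABCA3 were 10.7-fold and 10.0-fold above the control line. 1034 genes were lower than in both other groups, 333 at least 2-fold in each, and the DUX4 effect had not passed for 541. MYC stood at 3.83 ± 1.59 CPM with iP300w, 33.1 ± 11.7 in the DUX4 line and 70.8 ± 4.05 in the control line. TFRC, the transferrin receptor, stood at 83.4 ± 15.5, 736 ± 134 and 295 ± 38.1 CPM, and TIMP3 at 36.2 ± 13.3, 149.7 ± 19.1 and 152 ± 12.7 CPM. Both contrasts use the same iP300w libraries, which favours such genes. How many such genes this alone would give was not computed, and the counts were made with TMM scaling only.

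ZSCAN4 kept 66.0% of its DUX4-line level with iP300w where LEUTX kept 0.0589%. The ratio was 1120.4 over the 23 targets with at least 1000 counts in the DUX4 libraries (132 without ZSCAN4). The 132 rests on PRAMEF1 at 7.78%, whose log2 fold change with iP300w moved from -3.68 to -4.47 without iP300w library 5. Reads carried over from the DUX4 libraries would add about the same share to every target, so at most the 0.0589% that LEUTX kept; in the iP300w libraries LEUTX had 4 to 22 counts and ZSCAN4 26967 to 44383, which argues against carry-over as the source of the ZSCAN4 level. Reads shared between near-identical copies would not spread the 7 targets outside the repeated families. ZSCAN4 and LEUTX are both among these, so their ratio is the same 1120.4 and no second test. Without ZSCAN4 it is 14.2. A candidate explanation left open is that activation of ZSCAN4 by DUX4, or the life of its transcript, depends less on p300 than that of other targets; no value here tests this. Among the listed targets it rests on 1 gene, and the ZSCAN4 change ranged from -0.90 (without iP300w library 5) to -0.02 (total counts alone). Outside the list, ZNF705A had 0 counts in the control line and was at least 2649-fold above it with DUX4 and 856-fold with iP300w. MRAP2, also at 0 counts there, was at least 2122-fold and 33.5-fold above it. The ZNF705A values are uncertain, since near-identical copies share reads.

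Fold changes followed GC content: with DUX4 the median log2 fold change fell from 0.69 in the fifth of genes with the lowest transcript GC to -0.70 in the highest (Spearman -0.37 across 12364 genes), and with iP300w it ran from -0.48 to 0.47. With offsets that remove the GC trend, 2191 genes that rose with DUX4 still moved back, against 2461 without them, which argues against GC bias as the whole of the reversal. With total counts alone 1543 genes moved back among those that rose and 3414 among those that fell, so scaling does not make the reversal, though it sets the balance of its directions. The control and DUX4 libraries did not overlap in GC trend (gap 0.228), which a bias that goes with the groups and a change in the cells would both give. They cannot be told apart, because all libraries of a group share their treatment.

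Libraries of the DUX4 line may share an origin across the iP300w groups. Deviations from the group mean correlated at 0.589 between libraries 1 and 4, 0.581 between 2 and 5 and 0.443 between 3 and 6, and at -0.10 to -0.48 for other pairs (8676 genes). NDN had 0 counts in libraries 1 and 4 and 572 to 1083 in libraries 2, 3, 5 and 6; BACE2 had 0, 6 and 138 counts in libraries 1 to 3 and 0, 18 and 182 in 4 to 6; PCOLCE2 had 165, 0 and 79, then 127, 1 and 53. In control libraries 24, 25 and 26 NDN and BACE2 had 0 counts, and PCOLCE2 had 6, 15 and 16. These 3 genes, 100% of those at 1 count or less in some and 100 or more in other libraries of both groups, were off in the same partner libraries (2 under the best other pairing). NDN and BACE2 were off in libraries 1 and 4 and PCOLCE2 in 2 and 5, and none was off in 3 and 6. A shift that only scales counts would not take NDN from 0 to 572 counts. The genes were picked for such a change, so they cannot decide whether a shift of preparation is shared by the libraries. For the correlation across the 8676 genes, separate sources of cells and a shared shift cannot be told apart, since 3 genes are too few and the labels give these libraries no common number.

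For each comparison of 3 libraries against 3, 1 of the 10 splits, the real one, called as many genes with edgeR: 9002 for DUX4, 7405 for iP300w and 7594 for the last comparison, with 0 as the highest of the other splits. In those other splits at most 72, 259 and 190 genes had an unadjusted p under 0.05 and limma-voom called 0. Moving back was counted over 20 assignments of the 6 libraries of the DUX4 line: 1 of 20, the real one, gave as many, at 2461 and 2190 genes, and the highest others were 424 and 491, from the full swap of the groups. These splits are too few for a share under 0.05. All splits but the real one and the full swap also mix libraries of both groups on each side. This widens the spread within a side, so few or no calls were fixed in advance and nothing is concluded from them.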
